A study of Mus musculus with 11 samples.

How the data were processed

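Total RNA from kidney S3 proximal tubules of mice of a single inbred strain was extracted with the Arcturus PicoPure kit, a kit for very small tissue samples, and labelled with biotin by the Affymetrix WT Pico kit, per the labels' protocols. The series holds 11 arrays, 6 from wild-type and 5 from Tamm-Horsfall protein knockout mice, with the genotype, the replicate number and the batch taken from the labels. The deposited table holds log2 values, which per the submitters' processing notes involved Partek 6.6 and RMA, a method that corrects background, brings arrays to a like distribution and summarises the oligonucleotides of each probe set. RMA draws array distributions together, which can shrink a change shared by most genes, and amplification of such small RNA amounts adds spread between arrays. Whether a batch correction or a filter was applied before deposit, and which genome build the probe annotation used, is not given in the sources used here. The deposited log2 values ran from 0.79 to 14.08 over 41345 probes. Array medians lay between 3.85 and 4.01, and no values of background or detection were used.

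Probes were named from the platform annotation: 23521 carried 1 gene symbol, 1814 carried several and were not used for names, and 16010 carried none. For gene lists, 1 probe per gene was kept, that with the highest mean over all arrays, which gave 22180 genes. Of the 824 symbols in the lists 737 matched a probe. Genomic positions are not reported.

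Each probe was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, genotype and batch as fixed terms, two-sided, no filter on dim probes), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The fit had 8 residual degrees of freedom and a prior of 2.90. Folds are 2 to the power of the batch-adjusted log2 change. The batch term itself had 0 probes past the threshold and 2714 at an unadjusted p under 0.05. The same test, run on simulated data with 200 changed probes, recovered 65 of 100 at a log2 change of 1 and 90 of 100 at 2, with 12 false calls, and made 1 call when nothing was changed. Single values and list means were tested with two-sided exact permutation tests of genotype within batches (168 arrangements). Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 38 lists with at least 5 measured genes, and again with the correlation estimated for each list and with fry. The limma p of list members was also adjusted over each list alone, which makes no allowance for the number of lists, so some members pass by chance. Members that passed in this way did not pass over all probes. In simulated data a shift of 0.5 in a single list was recovered with no other list called, but the simulated genes vary independently, and other splits of the real arrays into 6 and 5 called a median of 5 lists. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

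Before the data were examined, the test, the 40 gene lists, the other settings to try and the rule for naming genes were fixed. The rule named Umod and Trpm2, then 10 genes in each direction, by largest change among those past the threshold and otherwise by smallest p, and up to 4 members with the smallest p of each list described. Predicted genes were skipped, which left out 3, and probes with several symbols or none were not named. The lists covered the TRPM2 pathway, oxidative and protein stress, inflammation, injury, metabolism, tubule segments, other kidney and blood cell types, and sex. Other settings fixed then were the model without batch, batch as a random block, batch 1 alone, the replicate number as a block, filters on dim probes, quantile normalization, median centring, array weights, a trended and robust prior, the thick ascending limb score as a covariate, 1 probe per gene, other thresholds, and each array left out in turn. Wild-type replicate 6 is the only wild-type array of batch 2. With the batch term, leaving it out therefore bases the genotype change on batch 1 alone. Settings chosen after seeing the data were annotated probes alone, the S3 minus S1 and S2 score or the first principal component as a covariate, and leaving out the 2 arrays at the ends of that component.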

Results

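Gene expression was measured in the S3 segment of the kidney proximal tubule, the straight part of the tubule that lies in the outer medulla, in mice of a single inbred strain. The comparison was between 6 arrays from wild-type mice and 5 arrays from mice lacking Tamm-Horsfall protein. Tamm-Horsfall protein, also called uromodulin and encoded by Umod, is made mainly by the thick ascending limb, which runs next to S3 tubules. The series title concerns circulating uromodulin, oxidative stress and the TRPM2 channel, so the comparison asks how S3 transcripts differ when uromodulin is missing. The arrays were run in 2 batches, with 5 wild-type and 3 knockout arrays in batch 1 and 1 wild-type and 2 knockout arrays in batch 2. The labels do not say that each array came from a separate mouse, so the p-values measure the spread between these arrays. Each array gave a log2 signal for 41345 probes, with array medians between 3.85 and 4.01, and the number of arrays limits the precision. Correlations between arrays over all probes ran from 0.901 to 0.955, and no arrays held identical values.

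Umod (Entrez 22242, probe 17495637) had lower signal in knockout than in wild-type arrays. Its mean log2 signal was 5.80 ± 0.579 (SD, n = 6) in wild type and 4.49 ± 0.582 (SD, n = 5) in knockout. The batch-adjusted log2 change was -1.52 ± 0.24 (SE), with a 95% interval from -2.06 to -0.98. The change was -1.41 within batch 1 and -1.83 within batch 2. A two-sided exact permutation test within batches gave p = 0.00595, the smallest p that its 168 arrangements allow, and among all probes the limma adjusted p with Benjamini-Hochberg was 0.281. The wild-type arrays read 5.80, 5.27, 6.20, 5.53, 5.27 and 6.74 for replicates 1 to 6. The knockout arrays read 3.68, 4.26, 4.67, 4.55 and 5.27 for replicates 1 to 5, so knockout replicate 5 equalled the lowest wild-type arrays. Whether the Umod probe lies inside the deleted part of the gene is not given in the sources used here, so the remaining signal in knockout arrays does not measure intact transcript. That signal was not shown to be above background, so no fold is given. Because Umod is made mainly by the thick ascending limb, RNA of that segment captured with S3 may contribute to the Umod signal. How much it contributed in each array was not measured, so single Umod values need not reflect genotype alone.

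Trpm2 (Entrez 28240, probe 17242335), which encodes a calcium-permeable channel opened by ADP-ribose under oxidative stress, did not differ detectably between genotypes. Its mean log2 signal was 3.66 ± 0.209 (SD, n = 6) in wild type and 3.57 ± 0.0568 (SD, n = 5) in knockout, below the median probe of every array. The log2 change was -0.06 ± 0.12 (SE), with a 95% interval from -0.32 to 0.20, a limma adjusted p of 0.946 and an exact within-batch permutation p of 0.542. The change was -0.09 within batch 1 and 0.02 within batch 2.

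**Figure D1:**
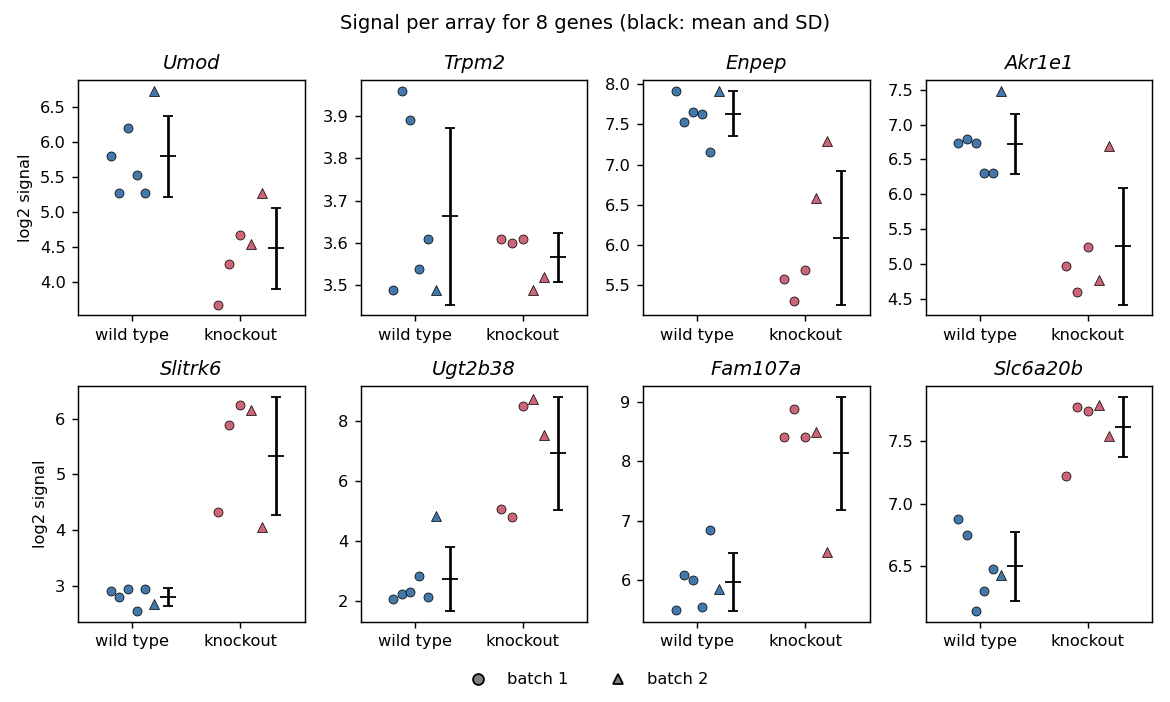
Log2 signal per array (vertical axis) for Umod, Trpm2 and 6 other genes in 6 wild-type and 5 knockout arrays, with circles for batch 1, triangles for batch 2, and black marks for the mean and SD of each group. Umod averaged 5.80 in wild type and 4.49 in knockout, Trpm2 averaged 3.66 and 3.57, and for Slitrk6 every knockout array lay above every wild-type array.

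None of the 10 genes with the smallest p among those higher in knockout passed the threshold over all probes. Ugt2b38, a UDP-glucuronosyltransferase, had a fitted log2 difference of 3.68 ± 0.60 (SE), which was 2.83 without knockout replicate 3, with a mean of 2.73 in wild type and 6.93 in knockout. Slitrk6, a transmembrane protein with leucine-rich repeats, had a fitted log2 difference of 2.59 ± 0.41, going from 2.81 ± 0.162 (SD, n = 6) to 5.33 ± 1.06 (SD, n = 5) without overlap between the groups. The wild-type means of Ugt2b38 and Slitrk6 lay below the lower quartile of every array (2.85 to 3.03) and were not shown to be above background, so no fold is given for them and the fitted differences are no exact measure of size. Slco4c1, an organic anion transporter of the kidney, was higher by 2.53 ± 0.44 on the log2 scale, from a wild-type mean of 3.47 below every array median, and Fam107a, an actin-associated protein, was higher by 2.32 ± 0.38 (SE) on the log2 scale. Mid1, a ubiquitin ligase, was 3.66-fold higher and Slc6a20b, a member of the sodium-coupled amino acid carriers, 2.16-fold higher, both without overlap between groups. The transcription factor Ets2 (log2 change 0.98), the sterol synthesis enzyme Nsdhl (0.93), the sorting nexin Snx31 (0.90) and the tetraspanin Tspan33 (0.87) completed the 10 genes, again without overlap. The limma adjusted p of these 10 genes ran from 0.271 to 0.324 with Benjamini-Hochberg over all probes. Without knockout replicate 5 Slitrk6, Fam107a and Slco4c1 passed the threshold (adjusted p = 0.0346, 0.0213 and 0.0213), and without knockout replicate 3 Ugt2b38 passed it at that smaller change (adjusted p = 0.0223). Ugt2b38 and Slc6a20b have close relatives of similar sequence that could share their probe signal, so their identity is less certain.

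The gene with the lowest p was Enpep (Entrez 13809), which encodes glutamyl aminopeptidase, the brush-border enzyme that cleaves angiotensin II. It was 3.41-fold lower in knockout, at 7.63 ± 0.281 (SD, n = 6) in wild type and 6.09 ± 0.829 (SD, n = 5) in knockout. Its log2 change of -1.77 ± 0.22 (SE) had a limma adjusted p of 0.0813. Akr1e1, an aldo-keto reductase, was 3.19-fold lower (-1.67 ± 0.30), Dap, the death-associated protein, 2.30-fold lower, and the retinol dehydrogenase family member Rdh16f2 2.25-fold lower. Thnsl2, a threonine synthase-like protein, was 1.91-fold lower, and the cytochrome P450 gene Cyp4a31 1.80-fold lower. Its relative Cyp2a12 had a log2 change of -0.51 between dim signals, 3.34 in wild type and 2.85 in knockout, which were not shown to be above background. The calcium-binding protein S100a11 was 1.62-fold lower and its pseudogene S100a11-ps 1.72-fold lower. S100a11 and S100a11-ps are near-identical, so their signals cannot be separated, and the Cyp4a, Cyp2a and Rdh16 families raise the same doubt. The limma adjusted p of the other lower genes, Umod included, ran from 0.281 to 0.518. Of the 21 genes named to this point, 20 had the same sign within both batches, with Trpm2 as the exception. All but Umod and Trpm2 were named only for their small p in these same arrays, so this agreement is no independent support. Batch 2 also held only 1 wild-type and 2 knockout arrays. Enpep was at -2.05 within batch 1 and -0.98 within batch 2, and it passed the threshold without knockout replicate 5 (adjusted p = 0.0213) and without wild-type replicate 6 (adjusted p = 0.0326). Leaving out wild-type replicate 6, the only wild-type array of batch 2, bases the change on batch 1 alone. Akr1e1 passed the threshold without knockout replicate 5 (adjusted p = 0.0346).

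In total, limma found 0 of the 41345 probes past an adjusted p of 0.05, and the smallest adjusted p was 0.0813, shared by 4 probes. At an unadjusted p under 0.05 there were 2546 probes, 1405 higher and 1141 lower in knockout, where 2067 are expected by chance. Of the 10 probes with the smallest p, 4 carried no gene in the annotation. The count of probes past the threshold was 11 without knockout replicate 5, 3 without wild-type replicate 6, 2 without knockout replicate 3 and 1 without wild-type replicate 1. The count without wild-type replicate 6 rests on changes within batch 1 alone, because batch 2 then holds no wild-type array. Of the 11 without knockout replicate 5, 6 carried 1 gene symbol. The probe with the smallest adjusted p there carried none (log2 change 3.99, limma adjusted p = 0.000413). In simulated data on all 11 arrays the same test recovered 65 of 100 probes changed by 1 on the log2 scale and 90 of 100 changed by 2. There 200 probes changed at once and probes varied independently. With many changed probes the adjustment is less strict than with few, so these shares may overstate what could be found here.

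Genes for heat shock proteins and chaperones, which fold proteins and respond to proteotoxic stress, had higher signal in knockout S3 tubules as a group. Of the 15 measured members of the heat shock and chaperones list, 14 were higher and 1 lower, with a mean log2 change of 0.42. The examples with the smallest p were the inducible chaperone Hspa1a (0.75 ± 0.23, SE), the constitutive chaperone Hspa8 (0.36 ± 0.11), Hsp90aa1 (0.43 ± 0.15) and the small heat shock protein Cryab (1.06 ± 0.39). Cryab is also a member of the thin limb marker list, and its lowest change over the settings other than leaving out an array was 0.36. The mean of the heat shock and chaperones list was 5.11 ± 0.194 (SD, n = 6) in wild type and 5.58 ± 0.256 (SD, n = 5) in knockout, and the change was 0.44 within batch 1 and 0.37 within batch 2. The camera adjusted p was 5.21e-06 with the preset correlation, and adjusted p = 0.48 with an estimated correlation. An exact within-batch permutation test of the list mean gave p = 0.00595, the smallest possible, and 0.238 after Benjamini-Hochberg over the lists. No member passed over all probes, and 0 members passed adjusted over the list alone, where the smallest adjusted p was 0.0589. With the preset correlation, the list stayed past the camera threshold without each array in turn.

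Lists of antioxidant and unfolded protein response genes passed camera with the preset correlation only, both towards higher signal in knockout. In the list of NRF2 targets and antioxidant enzymes 24 of 30 genes were higher, with a mean log2 change of 0.17 (0.16 within batch 1 and 0.17 within batch 2). Gclc, which limits the rate of glutathione synthesis, was at 0.84 ± 0.28 (SE), glutathione synthetase Gss at 0.30 ± 0.13, the oxidative stress growth inhibitor Osgin1 at 0.27 ± 0.12 and thioredoxin reductase Txnrd1 at 0.27 ± 0.13. The camera adjusted p was 0.00624, with adjusted p = 0.771 with an estimated correlation. In the unfolded protein response list 20 of 24 genes were higher, with a mean of 0.17 (0.17 within batch 1 and 0.18 within batch 2), led by the endoplasmic reticulum chaperones Dnajb11 (0.57 ± 0.20) and Calr (0.35 ± 0.14), the ubiquitin ligase Syvn1 (0.26 ± 0.11) and the sensor Atf6 (0.70 ± 0.36). Its camera adjusted p was 0.0134, with adjusted p = 0.771 with an estimated correlation. In both lists 0 members passed, over all probes and adjusted over the list alone. Exact within-batch permutation tests of the list means gave p = 0.179 for the NRF2 list and 0.0238 for the unfolded protein response list, or 0.640 and 0.317 after Benjamini-Hochberg over the lists. Without knockout replicate 3 the mean of NRF2 target and antioxidant enzymes was 0.09 (camera adjusted p = 0.282) and that of Unfolded protein response 0.11 (camera adjusted p = 0.263). Without wild-type replicate 6, where the change rests on batch 1 alone, the unfolded protein response mean was 0.17, with a camera adjusted p of 0.0754. Both calls were also lost with the S3 minus S1 and S2 marker score as a covariate, where the means were 0.10 and 0.14 (camera adjusted p = 0.237 and 0.141). Over the settings other than leaving out an array, the lowest means were 0.045 for the NRF2 list and 0.095 for the unfolded protein response list.

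Lists of lipid metabolism genes also passed camera with the preset correlation alone, in the same direction. Cholesterol and sterol synthesis genes had a mean log2 change of 0.34, with 14 of 15 genes higher. Nsdhl (0.93 ± 0.18, SE) and Hmgcs1, the HMG-CoA synthase of the sterol pathway (1.51 ± 0.37), passed adjusted over the list alone (limma adjusted p = 0.00411 and 0.013), while Mvd was at 0.38 ± 0.14 and Insig1 at 0.32 ± 0.19. The list mean differed by 0.46 within batch 1 and by 0.03 within batch 2, and its camera adjusted p was 0.00401, with adjusted p = 0.771 with an estimated correlation. Peroxisome genes had a mean change of 0.20, with 18 of 24 higher (0.22 within batch 1 and 0.15 within batch 2). The branched-chain acyl-CoA oxidase Acox2 (1.29 ± 0.31) and the racemase Amacr (0.74 ± 0.20) passed adjusted over the list alone (limma adjusted p = 0.036 and 0.0455), with Hacl1 at 0.40 and Crot at 0.86. For peroxisome genes the camera adjusted p was 0.0134, with adjusted p = 0.771 with an estimated correlation. Fatty acid oxidation genes had a mean change of 0.17, with 24 of 28 higher (0.14 within batch 1 and 0.24 within batch 2). Cpt2, Slc25a20 and Acadl, which move or oxidise acyl chains in mitochondria, were at 0.49, 0.39 and 0.50, whereas the thiolase Acaa2, the member with the smallest p, was lower at -0.72 ± 0.21. This list had a camera adjusted p of 0.0175, with adjusted p = 0.771 with an estimated correlation, and 0 members passed in either count. Exact within-batch permutation p of the list means was 0.125 for cholesterol, 0.137 for peroxisome and 0.226 for fatty acid oxidation genes, each 0.640 after Benjamini-Hochberg over the lists. Without knockout replicate 3 the means were 0.22, 0.11 and 0.07, and the calls were lost (adjusted p = 0.263, 0.339 and 0.339), as were the peroxisome call without wild-type replicate 4 (0.0593) and the fatty acid oxidation call without wild-type replicates 4, 5 or 6 or knockout replicate 4 (0.0538 to 0.198). All 3 calls were also lost with the S3 minus S1 and S2 marker score as a covariate, where the mean was 0.07 for Cholesterol and sterol synthesis, 0.19 for Peroxisome and 0.13 for Fatty acid oxidation and PPAR-alpha targets (adjusted p = 0.683, 0.0691 and 0.157). Over the settings other than leaving out an array, the lowest mean was 0.04 for peroxisome genes and 0.005 for fatty acid oxidation genes.

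Smaller mean changes were found for 3 further lists. Oxidative phosphorylation genes were higher in 30 of 40 cases, with a mean of 0.13 (0.10 within batch 1 and 0.21 within batch 2), including Ndufs7 (0.43), Cox6a1 (0.33), Ndufv1 (0.37) and Cox6b1 (0.57). Its camera adjusted p was 0.0248, with adjusted p = 0.833 with an estimated correlation. Lysosome and autophagy genes were higher in 22 of 25 cases, with a mean of 0.15 (0.14 within batch 1 and 0.17 within batch 2), including the cathepsins Ctsh (0.38) and Ctsb (0.32) and the autophagy genes Atg5 (0.66) and Becn1 (0.19). The camera adjusted p was 0.0279, with adjusted p = 0.771 with an estimated correlation. Circadian clock genes were higher in 15 of 18 cases, with a mean of 0.13 (0.13 within batch 1 and 0.15 within batch 2), including the deubiquitinase Usp2 (0.34), the nuclear receptor Nr1d2 (0.32) and the clock output factor Dbp (0.27), while Npas2 was lower at -0.35. The clock list had a camera adjusted p of 0.0478, with adjusted p = 0.771 with an estimated correlation. In these 3 lists 0 members passed, over all probes and adjusted over the list alone, and the exact within-batch permutation p of the list mean was 0.583, 0.196 and 0.0774 in the same order. All 3 calls were lost with the S3 minus S1 and S2 marker score as a covariate, where the mean of Mitochondrial oxidative phosphorylation turned to -0.06, that of Lysosome and autophagy was 0.09 and that of Circadian clock 0.17 (adjusted p = 0.624, 0.433 and 0.0528). Over the settings other than leaving out an array, the lowest mean was 0.03 for lysosome and autophagy genes and 0.08 for clock genes. The oxidative phosphorylation mean also turned to -0.11 with the first principal component as a covariate, to -0.06 with the replicate number as a block and to -0.05 without knockout replicate 3, and its call was also lost without wild-type replicates 3, 4 or 6 or knockout replicate 4. The lysosome call was lost without wild-type replicates 4, 5 or 6 or knockout replicates 3 or 4 (adjusted p = 0.0538 to 0.447), with a mean of 0.07 without knockout replicate 3, and the clock call without any array but wild-type replicate 3 and knockout replicates 2 and 5 (0.0551 to 0.282), although the clock mean stayed between 0.10 and 0.13 there.

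Marker genes of the proximal tubule segments lay in opposite directions over all arrays and within batch 1, but not within batch 2, where both list means were above 0. S3 markers were higher in knockout in 19 of 21 cases, with a mean log2 change of 0.36. Slc22a7, an organic anion transporter of S3, was at 1.11 ± 0.34 (SE), the phospholipid flippase Atp11a at 0.45 ± 0.15, Mpv17l at 0.59 ± 0.23 and Nudt19 at 0.68 ± 0.28. The change was 0.44 within batch 1 and 0.15 within batch 2, and the camera adjusted p was 0.00183, with adjusted p = 0.771 with an estimated correlation. Markers of the earlier S1 and S2 segments were lower in 17 of 23 cases, with a mean of -0.19 and a camera adjusted p of 0.0279, with adjusted p = 0.771 with an estimated correlation. The organic anion transporter Slc22a8 (-1.78 ± 0.44) passed adjusted over the list alone (limma adjusted p = 0.0491), the lactate carrier Slc5a12 was at -0.63 ± 0.19 and the amino acid carrier Slc6a19 at -0.26 ± 0.15, whereas the glutamine carrier Slc38a3 was at 0.68 ± 0.29. The S1 and S2 mean differed by -0.27 within batch 1 and by 0.05 within batch 2, and without knockout replicate 2 it was 0.00. Over the settings other than leaving out an array, the S1 and S2 mean ran from -0.43 to -0.09. Exact within-batch permutation p was 0.173 for the S3 mean and 0.369 for the S1 and S2 mean. Without knockout replicate 3 the S3 mean was 0.21 and its call was lost (adjusted p = 0.263), while the S1 and S2 mean was -0.30, and the S1 and S2 call was lost without wild-type replicates 1, 2 or 3 or knockout replicates 1, 2 or 5 (0.0508 to 0.861). With the thick ascending limb score as a covariate the mean of S3 proximal tubule markers was 0.23, with the replicate number as a block 0.33 and with the first principal component 0.15, and the S3 call was lost each time (adjusted p = 0.124, 0.240 and 0.509). Thick ascending limb markers, with Umod left out, did not pass (mean 0.23, 13 of 18 higher, camera adjusted p = 0.131). Their list mean was 6.56 in knockout replicate 4 and at most 5.60 in the other 10 arrays, and Slc12a1, the sodium-potassium-chloride carrier of that segment, read 10.05 there against at most 7.54 elsewhere. Wnk1 (0.52), Cldn19 (0.50), Bsnd (0.41) and Slc12a1 (0.86) had the smallest p of that list. Without knockout replicate 5 the thick ascending limb list passed (camera adjusted p = 0.00158), and without knockout replicate 4 its mean was 0.09, with Slc12a1 at 0.52 and Bsnd at 0.26. The list's change was 0.19 within batch 1 and 0.35 within batch 2.

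**Figure D2:**
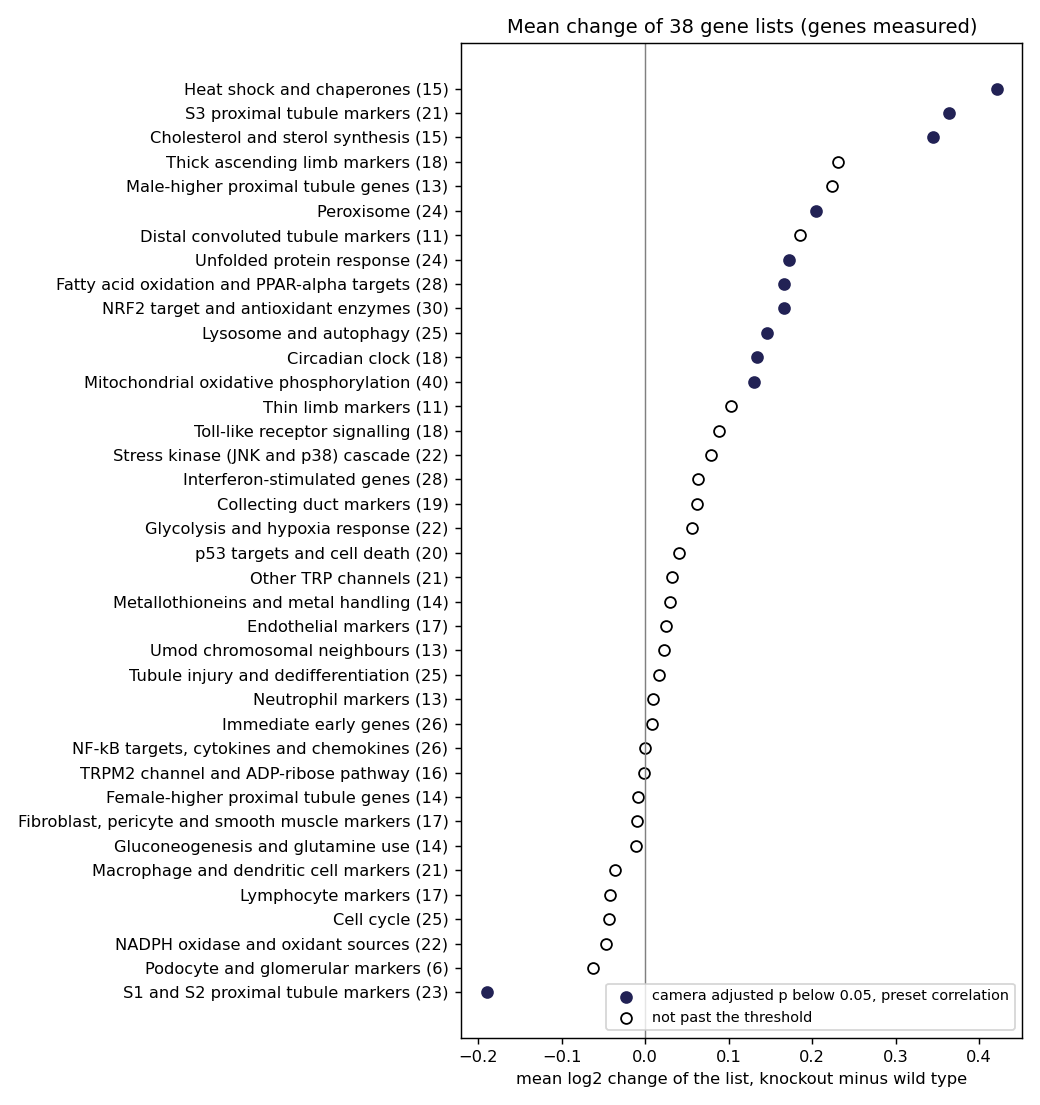
Mean log2 change, knockout minus wild type (horizontal axis), of the 38 gene lists tested, each named with its number of measured genes. Filled points passed a camera adjusted p of 0.05 with the preset correlation, and 0 lists passed with an estimated correlation. Heat shock and chaperones lay highest at 0.42 and the S1 and S2 markers lowest at -0.19.

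Genes of the pathway named in the title did not move together. The TRPM2 and ADP-ribose list had 5 genes higher and 11 lower, with a mean log2 change of 0.00, a median of -0.06 and a camera adjusted p of 0.601. Its members with the smallest p were the ADP-ribosyl hydrolase Adprhl2 (0.61 ± 0.19, SE), Oard1 (-0.26 ± 0.12), the ADP-ribose pyrophosphatase Nudt9 (-0.21 ± 0.11) and the mitochondrial deacetylase Sirt3 (0.25 ± 0.16), and 0 members passed adjusted over the list alone. NADPH oxidases and other oxidant sources had 11 genes higher and 11 lower (mean -0.05, camera adjusted p = 0.426). Fry's mixed test, of changes in either direction, passed this list (mixed adjusted p = 0.0451), which does not show that most members changed. Within the list 0 members passed over all probes. The peroxisomal hydroxyacid oxidase Hao2 (-1.05 ± 0.25) passed adjusted over the list alone (limma adjusted p = 0.0299), and Dao (0.41), Nox1 (-0.26) and Cybb (0.29) did not. The JNK and p38 list was at a mean of 0.08 (14 of 22 higher, camera adjusted p = 0.484), with the kinase Map2k4 at 0.61 ± 0.16, Atf2 at 0.39, Mapk13 at 0.17 and Mapk10 at -0.19. NF-kB targets, cytokines and chemokines had 12 genes higher and 14 lower (camera adjusted p = 0.614). Of these the chemokine Cxcl12 (1.12 ± 0.27) passed adjusted over the list alone (limma adjusted p = 0.0413), while Ccl2 (-0.52 ± 0.16), Icam1 (0.25) and Il1a (-0.27) did not. Tubule injury genes had 12 higher and 13 lower (camera adjusted p = 0.993), with a mean of 0.02, a median of 0.00 and a camera direction towards lower, relative to the other genes. The lipid droplet protein Plin2 was at 0.43 ± 0.11, the injury marker Havcr1 at -0.85 ± 0.25, Krt8 at 0.26 and Anxa3 at 0.29, and none of them passed adjusted over the list alone.

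**Figure D3:**
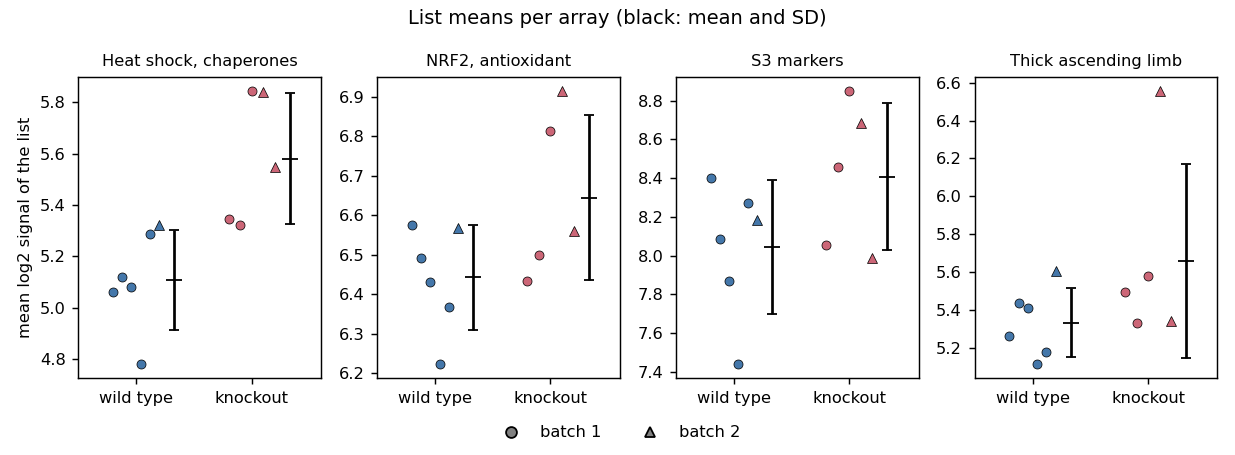
Mean log2 signal per array (vertical axis) of 4 gene lists in 6 wild-type and 5 knockout arrays, with circles for batch 1, triangles for batch 2, and black marks for the mean and SD of each group. The heat shock and chaperones mean was 5.11 in wild type and 5.58 in knockout, and knockout replicate 4 lay apart in thick ascending limb markers at 6.56.

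Of the 38 lists tested, 11 passed the camera threshold with the preset correlation, 10 higher and 1 lower in knockout, and 0 passed with an estimated correlation or with fry's test of a shift in a single direction. Fry's mixed test, of changes in either direction, passed 2 lists, heat shock and chaperones (adjusted p = 0.0309) and NADPH oxidase and oxidant sources (0.0451). The count of lists past the camera threshold fell to 2 without knockout replicate 3, to 6 without wild-type replicate 4 and to 7 without knockout replicate 4. It was also 6 without wild-type replicate 6, as with batch 1 alone, because batch 2 then holds no wild-type array. With the first principal component, the thick ascending limb score or the S3 minus S1 and S2 score as a covariate, 4, 2 and 1 lists passed, and the heat shock and chaperones list was past the threshold each time. It was the only higher list to pass with the thick ascending limb score or with the replicate number as a block.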

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

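The tests on knockout replicate 5 were chosen after the result was seen. Of 210 groups of values tested for a single array far from the rest of its genotype, 15 passed Dixon's 95% critical value, where 10.5 are expected by chance, so chance can account for most of them, and the largest share of gap over range was 0.938. Among the wild-type arrays, replicate 6 was far above the others in Ugt2b38 (4.85 against at most 2.82, 0.730 of the range) and far below them in Ets2 (3.91, 0.732) and Icam1 (5.01, 0.938). Wild-type replicate 5 was lowest in Dap (6.77, 0.697) and in the S1 and S2 markers (6.76, 0.774) and highest in Anxa3 (3.36, 0.685), and wild-type replicate 4 was lowest in Nudt19 (6.78, 0.730). Knockout replicate 1 was lowest in Nudt9 (5.29, 0.720) and knockout replicate 3 highest in Slc25a20 (6.66, 0.725). Knockout replicate 4 was highest in Krt8 (6.73, 0.816), in the thick ascending limb genes Slc12a1 (10.05, 0.826) and Bsnd (6.53, 0.781), and in the mean of that list (6.56, 0.801). Knockout replicate 5 was lowest in Fam107a (6.47, 0.801) and Mapk13 (4.47, 0.843).

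Knockout replicate 5 lay between the genotypes at the 11 probes that passed the threshold without it, nearer to wild type on the log2 scale at 10 of them, with a median position of 0.194 between wild type (0) and the other knockout arrays (1). With all arrays 0 probes passed, and this array was singled out because leaving it out gave the most. Probes that pass only without an array tend to be those where it lies towards the other genotype. These positions, and the wild-type shares at the same probes, therefore follow in large part from the choice of probes. Knockout replicate 5 was near wild type at Enpep (7.30 against 5.79 in the other knockout arrays and 7.63 in wild type), Akr1e1 (6.69 against 4.89 and 6.73) and Slco4c1 (3.84 against 6.31 and 3.47), and farther from it at Slitrk6 (4.05 against 5.65 and 2.81) and at an unnamed probe (9.32 against 10.44 and 7.83). A wild-type sample under a knockout name stays open: this array lay outside the wild-type range on the knockout side at 5 of these probes, Slitrk6 included, while wild-type arrays left out in the same way, each with its 11 probes of smallest p, did so at 1 to 8 (mean 4.83, SD 2.71), although against a range of 5 arrays in place of 6. Wild-type RNA mixed into a knockout sample stays open as well: the wild-type share on the linear scale was 0.525 at Umod, with a bootstrap interval from 0.325 to 0.820, and between 0.644 and 0.999 at the 11 probes. Chance stays open too, because the median position over the 20 probes with the smallest p in the other arrays was 0.280 (0.172 to 0.401), while knockout replicate 2, left out in the same way, gave 0.447 with an interval from 0.218 to 0.663. Wild-type arrays left out in turn gave 0.014 to 0.481, a range that holds both values, and knockout replicates 1, 3 and 4 gave 0.660 to 0.891. The intervals of these positions are bootstraps over the 20 probes within 1 array and do not measure the spread between arrays. A biological difference between knockout mice was not tested.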

How the results depend on the processing

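Annotated probes alone, the S3 minus S1 and S2 score, the first principal component and leaving out the 2 arrays at its ends were chosen after seeing the data. Over all settings, the values of named genes and lists kept their direction and their side of the threshold 2642 times, lost a call 122 times, gained a call 13 times and turned 23 times. These counts do not measure stability, because no named gene passed in the main fit. Only the 11 lists past the camera threshold had a call to lose, and all 122 losses fell on them. The log2 change of Umod kept its direction and stayed short of the threshold in all 27 settings that gave it (-1.70 to -1.29), and so did Trpm2 in all 26 (-0.17 to -0.01). The count of 0 probes past the threshold became 3 with batch 1 alone, 1 with 1 probe per gene or with annotated probes alone (Enpep, adjusted p = 0.0310 and 0.0438, with fewer probes tested), 4 at an adjusted p of 0.10, and 0 to 11 with each array left out in turn. It stayed at 0 in the other settings. The count of 11 lists became 14 without batch or with batch as a random block, 6 with batch 1 alone, 4 without the dimmer probes, those below the median mean signal, 4 with quantile normalization, 2 with the thick ascending limb score, 1 with the S3 minus S1 and S2 score, 4 with the first principal component, 2 without the 2 arrays at its ends, 0 with an estimated correlation, 0 with fry, and 2 to 12 with each array left out in turn. The same replicate numbers do not pair the arrays, since the deviations of same-numbered arrays correlated at -0.181 to 0.0118 and no knockout array correlated best with its own number. With the replicate number as a block, which leaves 3 residual degrees of freedom, 0 probes and 2 lists passed, oxidative phosphorylation turned to -0.0639, Sirt3 to -0.0733, and fatty acid oxidation turned in camera direction, which is relative to the other genes (0.0280). The heat shock and chaperones list kept its call in 27 of 29 settings, all but the estimated correlation and fry (0.30 to 0.48). Those 27 all used camera's preset correlation of 0.01, while the correlation estimated for this list was 0.150. Without that preset the adjusted p was 0.480 with camera and 0.173 with fry. Oxidative phosphorylation also turned to -0.0627 with the S3 minus S1 and S2 score, -0.107 with the first principal component, -0.0353 without the 2 arrays at its ends, and -0.0464 without knockout replicate 3, the only array whose removal turned it (range over arrays left out -0.0464 to 0.289). With the first principal component the JNK and p38 list (0.00508), the injury list (0.0319) and the thick ascending limb list (0.0524) turned in camera direction. The injury list, never past the threshold, also turned without batch (0.0455), with batch as a random block (0.0487), in batch 1 (0.0421), with the replicate block (0.0797), with quantile normalization (0.0174), with median centring (0.0378), with fry (0.0164), and without wild-type replicates 3, 4, 5 or 6 or knockout replicates 1 or 5 (0.0131 to 0.0421, in a range of -0.0119 to 0.0421 over all arrays left out). Thick ascending limb markers passed without batch (adjusted p = 0.0285) and with batch as a random block (adjusted p = 0.0237). Camera compares a list with the other genes, while fry compares it with no change. The injury list's mean with fry, 0.0164, was that of the main fit, so only the comparison differed there. The cause of the other turns was not tested. The filters on dim probes removed some named genes, Cyp2a12 and Nox1 among them, which then have no value. Covariate settings gave no value for the lists that form the covariate. The sex covariate was not run, because Xist (2.35 to 2.96) and Eif2s3y (4.50 to 5.21) did not place the arrays in 2 sexes. No background or detection values were used, so genes near the array medians, Trpm2 included, may lie near background.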

Other observations

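The tests on neighbouring genes and on unadjusted counts, and the first principal component as a covariate, were chosen after the result was seen. None of the further gene groups described next passed the camera threshold. Toll-like receptor signalling genes were higher in knockout in 13 of 18 cases (mean log2 change 0.09, camera adjusted p = 0.257), with an exact within-batch permutation p of 0.0119 that became 0.238 over the lists. Genes higher in male proximal tubules were at 0.22 (10 of 13 higher, adjusted p = 0.0850), with the dipeptidase Cndp2 at 0.55, and genes higher in females at -0.01 (adjusted p = 0.669), where Hao2 was lower and passed adjusted over the list alone (limma adjusted p = 0.0191). Distal convoluted tubule markers were higher in 10 of 11 cases (mean 0.19, adjusted p = 0.145), at -0.01 within batch 1 and 0.73 within batch 2, and their mean was 6.29 in knockout replicate 4 against at most 5.64 in the other arrays. The chromosomal neighbours of Umod were at 0.02 (7 of 13 higher, adjusted p = 0.878). Interferon-stimulated genes (mean 0.06, adjusted p = 0.361), glycolysis and hypoxia genes (0.06, 0.601), p53 and cell death genes (0.04, 0.776), other TRP channels (0.03, 0.804), metal handling genes (0.03, 0.804), immediate early genes (0.01, 0.804), gluconeogenesis genes (-0.01, 0.993) and cell cycle genes (-0.04, 0.214) did not pass. Collecting duct markers (0.06, 0.747) did not pass either, and their mean was 5.32 in knockout replicate 4 against at most 4.71 in the other arrays. Nor did markers of thin limb (0.10, 0.804), endothelium (0.02, 0.872), fibroblasts and smooth muscle (-0.01, 0.669), macrophages and dendritic cells (-0.04, 0.669), neutrophils (0.01, 0.804), lymphocytes (-0.04, 0.264) and podocytes (-0.06, 0.522). Erythroid and sex chromosome lists had 2 and 4 measured genes and were not tested.

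The heat shock and chaperones list was higher in knockout while S3 markers were higher and S1 and S2 markers lower, so a shift in which tubules were captured was weighed against genotype. The list's mean change was 0.42 ± 0.13 (SE) and stayed at 0.305 ± 0.143 with the S3 minus S1 and S2 score as a covariate, at 0.350 ± 0.133 with the thick ascending limb score, and at 0.301 ± 0.122 with the first principal component, each over 2 standard errors. The smallest ratio of change to SE was 2.14, with the S3 minus S1 and S2 score. A mean of marker genes measures capture only in part, so these fits do not exclude capture as the whole cause. A thin limb score was not tried as a covariate, although Cryab belongs to both the thin limb markers and the heat shock and chaperones list. Genotype remains a hypothesis, with an exact within-batch permutation p of 0.00595, or 0.238 after Benjamini-Hochberg over the lists. The list was singled out because it ranked first in these same arrays, so chance stays open as well. Part or all of the change may come from capture, since the mean fell from 0.42 to 0.305 with the segment score, and stress during tissue handling was not tested.

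Other splits of the 11 arrays into 6 and 5 were drawn, 100 of the 462 possible with the real split included. The splits cannot test the count of probes past the threshold, since the real count is 0 and all 100 of 100 are as large by construction (highest other 2). Chance cannot be excluded for the count of lists past the camera threshold (real 11, median of the other splits 5, highest other 16, 25 of 100 as large) or for the count of probes at an unadjusted p under 0.05 (real 2546, highest other 4229, 15 of 100 as large).

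A hypothesis that a difference in genetic background beyond Umod, carried along in the knockout line, might place changed genes next to each other was tested with the 200 genes of smallest p. They formed 25 neighbouring pairs within 10 genes, against a median of 18 and a 95th percentile of 26 in 10000 random draws matched on mean signal (permutation p = 0.0779). Without predicted genes and pairs of the same gene family there were 21 pairs against a random median of 20 (permutation p = 0.429). Because 163 of the 200 genes are expected by chance at their p, this test leaves the hypothesis open.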
